A study of Mus musculus with 47 samples.

How the data were processed

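Olfactory epithelium, the sheet of nasal tissue that holds the odor-sensing neurons, was dissected from mice at 7 postnatal ages, P0, P3, P5, P7, P10, P14 and P21. RNA was extracted in TRIzol and polyadenylated RNA was made into Illumina mRNA sequencing libraries, per the labels' protocols. Wild-type animals (WT) carried the strain label C57BL/6J and the others the strain label OIVT;Kir2.1 (called Kir below). Kir2.1 is an inward-rectifier potassium channel, the product of the gene Kcnj2. The 47 libraries fell into 14 groups, 23 WT and 24 Kir libraries, with 3 or 4 per group. The labels do not say whether each library came from its own animal, so a p-value measures the spread between libraries, which may in part be technical.

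Groups were taken from the sample titles. WT P0 replicate 3 carried P0 in its title and P3 in its stage label, and it was placed in P0 because the series design lists 4 WT samples at P0 and 3 at P3; the other placing was run as an alternative. The titles also carried a prefix (cry3, cry4 or cry6) whose meaning is not given in the sources used here. All P0, P3, P14 and P21 libraries had the prefix cry4 and all P5 and P10 libraries cry6, while each genotype at P7 held 1 cry4, 2 cry6 and 1 cry3 library. The prefix was treated as a possible batch and entered every model, so its effect was estimated from the P7 libraries. In Kir at P7 the cry4 and cry3 libraries also had low Kcnj2. The prefix term can take up that difference and carry it into comparisons of ages with unlike prefixes.

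The deposited tables held whole-number counts per gene and, separately, TPM per gene, for 54532 genes with Ensembl identifiers and symbols. Per the submitters' processing notes, bcl2fastq 2.18, STAR 2.6.1c, RSEM and the mouse build mm10 were used; their other settings, among them the strand setting, are not given in the sources used here. The deposited counts also had 4 lines that name no gene, for unmapped, multiply mapped, featureless and ambiguous reads. These stayed out of library sizes and tests. Unmapped reads made up 1.31% to 33.49% of a library, multiply mapped reads 5.17% to 20.58%, reads outside genes 3.79% to 12.28% and ambiguous reads 2.91% to 3.80%. Multiply mapped reads were thus not counted to genes, so values of near-identical copies (odorant receptors, lipocalins, class I histocompatibility genes, Ifit3 and Ifit3b, ribosomal protein genes with pseudogenes) rest on the reads that could be placed. The TPM values, which the authors made with RSEM per the submitters' processing notes, share such reads among copies. Without a stated strand setting, reads from overlapping antisense genes cannot be told apart. Positions are those of GENCODE mouse release M21 on GRCm38, the build mm10; 54495 of the 54532 identifiers matched.

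Reads per library, counted over all lines of the table, ran from 12393965 to 40525578, and gene counts from 8107547 to 30385151. The cry6 libraries were deeper, at 19246688 to 30385151 gene counts, than the cry4 libraries, at 8107547 to 15461615, and the 2 cry3 libraries, at 9278156 and 10187993. Libraries of the same age carried the same mix of prefixes in both genotypes. No replicates were identical: over 57 pairs within groups, counts differed by 8.09 to 130.29 times the variance that sampling alone gives.

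The counts were tested with edgeR 4.0.16 (R 4.3.3), by quasi-likelihood F tests, two-sided, with TMM normalization, the filterByExpr filter, a mean per group and the prefix as covariate, in a single fit of all libraries. This left 19927 genes. P-values were adjusted by the Benjamini-Hochberg method over these genes and a gene was called at an adjusted p below 0.05. Errors of log2 fold changes are standard errors, and levels are counts scaled to the normalized library size (CPM) with SD. Effects averaged over ages are the mean of the 7 within-age Kir minus WT differences, each age weighted equally. Gene lists, 35 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and adjustment over the lists within each of 11 comparisons. The same test with the correlation estimated from the data was run as an alternative, and its adjusted p is given wherever it loses the call. A list score is the mean log2 CPM over the list in 1 library. Single values per library were compared by exact permutation tests, two-sided, or by 100000 permutations of genotype within age. Exact tests of the odorant receptor share between 2 groups double the smaller tail, and tests that permute within age count absolute differences at least as large. The self-test on simulated counts, drawn over 19237 genes, changed 200 genes in Kir P21 alone and another 200 by 1.5-fold in all Kir libraries. In Kir versus WT at P21 it recovered 75 of the 100 genes changed 2-fold there and 95 of the 100 changed 4-fold. For Kir versus WT averaged over ages it recovered 176 of the 200 genes changed 1.5-fold. Of 245 calls at P21 9 were false, and of 266 averaged over ages 17, that is, on genes changed in neither way; the calls left over fell on genes of the other changed set. Camera found the 1 simulated set that was raised and called 1 of 100 unchanged sets, at an unadjusted p below 0.05. Genes were simulated independently and without age or prefix effects, so this does not test calls on lists of correlated genes.

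The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named were Kcnj2; the 10 genes with the largest rise and the 10 with the largest fall in WT P21 versus P0 and in Kir versus WT averaged over ages, among called genes of at least 5 CPM whose P21 and P0 libraries did not overlap, or whose fitted genotype difference had the same sign at all 7 ages; up to 3 per direction at each age by the same rule; up to 4 members of each list by smallest adjusted p; and the 5 genes of smallest adjusted p for each interaction. Genes without an ordinary symbol were not named. Some members of the lists are not reported here. A gene with no count in a group was given a bound from a floor of 3 counts over the group, and a gene with 1 to 3 counts a ratio with an exact 95% interval; both cover counting error only.

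Alternatives changed 1 choice each, with exceptions. Limma on TPM changed the values together with the test (and, in 1 of its settings, the filter). The block used the P0, P3, P14 and P21 libraries only. Fits with fewer libraries also applied the filter anew, which left 17095 genes for only the 2 groups at P0. Where all libraries of a fit held the same prefix, no prefix term entered. Scaling was by relative log expression or upper-quartile factors, with no filter or a filter of 1 CPM in 10 libraries. Other tests were DESeq2 1.42.0 and limma on log2(TPM + 1) and log2(TPM + 0.1). Other models had no prefix term, only the 2 groups compared, a block of replicate numbers or a covariate of Y-linked expression. WT P0 replicate 3 was placed in P3, and each library was left out in turn. Another 3 alternatives were chosen after seeing the data. These were leaving out 2 Kir P10 libraries with many unmapped reads, leaving out 5 Kir libraries with low Kcnj2, and counting calls without ribosomal protein genes. Leaving out the low-Kcnj2 libraries selects on a measured gene, so its values describe those libraries and are not a test of the design. Replicate numbers were checked as pairs by whether libraries of the same number deviate together from their group means. At P3 they did, with correlations of 0.21, 0.26 and 0.25, each library closest to its own number. The numbers were therefore read as pairs there, from the data and not from the labels, and without a test against chance. For the counts of genes, other splits of the libraries into groups of the same sizes were fitted, up to 100 per comparison, with the dispersion trend held fixed.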

Results

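Polyadenylated RNA from mouse olfactory epithelium was sequenced at 7 ages from birth (P0) to P21 in wild-type (WT) mice and in mice labelled for Kir2.1 (Kir). Groups held 4 WT and 4 Kir libraries at P0 and P7, 3 WT and 4 Kir libraries at P10, and 3 of each at P3, P5, P14 and P21. Gene counts per library ran from 8107547 to 30385151. The design asks how expression changes over the first 3 weeks and how it differs in the Kir mice at each age.

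Kcnj2, the gene whose product is Kir2.1 (ENSMUSG00000041695, chromosome 11, 111066164 to 111076821), was higher in Kir at all 7 ages. In WT it stood at 53.4 ± 4.34 CPM at P0 (SD, n = 4) and 99.7 ± 5.37 CPM at P21 (n = 3). In Kir it stood at 543 ± 83.7 CPM at P0 (n = 4), 1060 ± 143 CPM at P10 (n = 4) and 499 ± 478 CPM at P21 (n = 3). Averaged over ages its log2 fold change was 3.63 ± 0.21 (edgeR adjusted p = 7.59e-14). Each Kir library lay above the WT libraries of its age. The level was lowest in 5 Kir libraries, P3 replicate 3, P7 replicates 1 and 4 and P21 replicates 1 and 2, at 132, 146, 173, 209 and 238 CPM, against 439 CPM or more in the others. The labels do not say whether these 5 share genotype or dosage with the others, so Kir means at P3, P7 and P21 mix both kinds. The difference was called at P21 (log2 fold change 2.32 ± 0.53, edgeR adjusted p = 0.0192) as at the other ages. The genotype difference of Kcnj2 was not called as changing with age (adjusted p = 0.837).

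**Figure D1:**
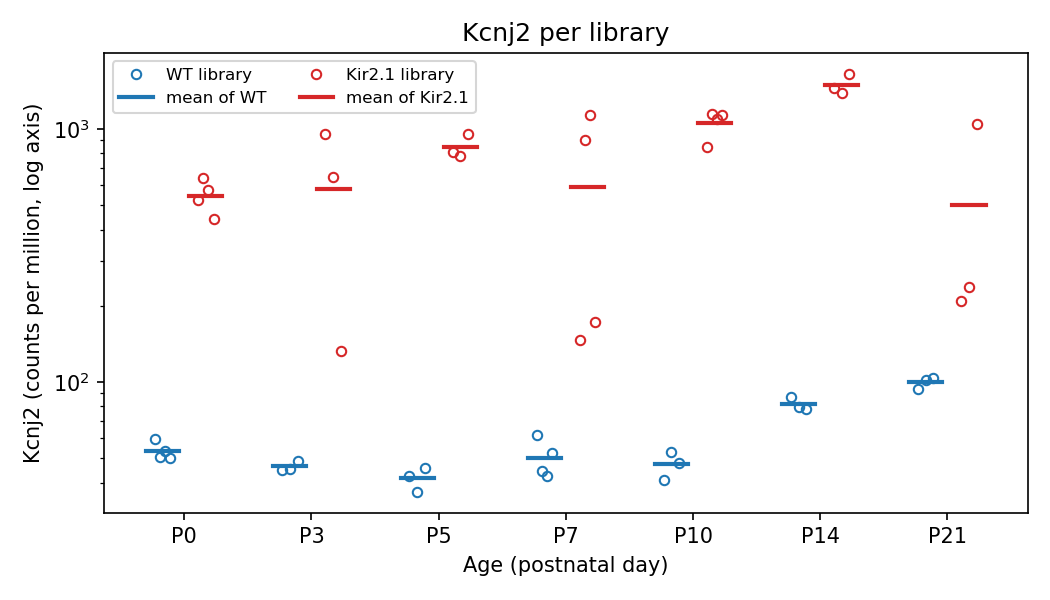
Kcnj2 in CPM (log axis) against postnatal age, a circle for each library and a line for each group mean, WT in blue and Kir2.1 in red. Each Kir library lies above the WT libraries of its age, and 5 Kir libraries, at 132 to 238 CPM, lie below the rest.

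In WT, genes of mature sensory neurons, odorant receptors and xenobiotic enzymes rose from P0 to P21, and genes of the cell cycle, of globose basal (neurogenic progenitor) cells, of Wnt signalling and of blood vessels fell. As lists these changes were called with the preset correlation, and with an estimated correlation 0 of 18 lists kept the call. Omp, the marker of mature olfactory sensory neurons, went from 355 ± 52.9 CPM (SD, n = 4) to 2430 ± 155 CPM (n = 3), a log2 fold change of 2.78 ± 0.18. Cyp2g1, an olfactory cytochrome P450 of sustentacular (supporting) cells, went from 703 ± 191 to 4660 ± 1200 CPM. Birc5, a mitotic gene, went from 24.2 ± 1.06 to 8.18 ± 0.823 CPM. In all, 10078 of 19927 genes were called, 4757 higher and 5321 lower at P21, of which 2242 and 2508 changed at least 2-fold. The larger part turned to higher calls with upper-quartile factors (5285 and 4754) and on log2(TPM + 1) (4943 and 3851).

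Among called genes of at least 5 CPM whose P21 and P0 libraries did not overlap, the 10 largest rises held 5 lipocalins of the odorant-binding kind (Lcn4, Obp1b, Obp2b, Lcn3 and Obp1a). Lcn4 (chromosome 2, 26667674 to 26671282) had no count in the 4 P0 libraries and was at least 7180-fold higher at P21, against a floor of 3 counts over the group. Obp1b had 3 counts over the P0 libraries and was 4500-fold higher (95% counting interval 1540 to 21800), and Moxd2, also with 3 counts, was 674-fold higher (230 to 3270). Obp2b rose from 4.16 ± 1.38 to 2020 ± 805 CPM, Lcn3 by a log2 fold change of 8.16 ± 1.60 and Obp1a by 8.15 (edgeR adjusted p = 0.00176). Srd5a2, a steroid 5-alpha-reductase, rose by 6.60 ± 0.30, from 1.12 ± 0.301 to 109 ± 2.71 CPM. Bglap (osteocalcin), Chil4 (a chitinase-like protein) and Mup4 (a major urinary protein) rose by 7.02 ± 0.88, 6.31 ± 1.65 and 5.78 ± 2.37. Adjusted p for these genes ran from 1.53e-18 for Srd5a2 to 0.0422 for Mup4.

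Of the 10 largest falls by the same rule 4 were in cartilage genes. Matn1 (chromosome 4, 130944385 to 130955475), a cartilage matrix protein, went from 5126 counts over the 4 P0 libraries to 1 count over the 3 P21 libraries, a ratio of 0.000236 (95% counting interval 5.97e-06 to 0.00132). The cartilage genes Ucma, Snorc and Clec3a fell to 1, 1 and 2 counts, ratios of 0.00106, 0.00136 and 0.00365. Agtr2 (an angiotensin receptor), Dlk1 (an imprinted growth regulator), Krt6a (a keratin) and Ubqlnl reached ratios of 0.00121, 0.00147, 0.00203 and 0.00369 by the same measure. Olfm5 fell from 2710 ± 720 to 14.2 ± 8.33 CPM and Apol10a from 58.5 ± 25.5 to 0.303 ± 0.241 CPM. Matn1 varied widely at P0, at 113 ± 149 CPM (SD, n = 4). The list of bone and cartilage genes split, with 9 members higher and 13 lower of 22 (also 9 and 13 adjusted over the list alone; camera adjusted p = 0.803). Bglap and Alpl, of bone, rose, while Col2a1 (-7.49 ± 1.10) and Col9a3 (-4.53 ± 0.65), of cartilage, fell.

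All 26 mature neuron genes rose (26 adjusted over the list alone), with a median log2 fold change of 1.90 (camera adjusted p = 2.83e-21, and adjusted p = 0.147 with an estimated correlation). Among them were the transduction genes Cnga4 (2.88 ± 0.18), Cnga2 (2.27 ± 0.14) and Pde1c (1.81 ± 0.13). Of 997 odorant receptor genes 613 rose and 6 fell (632 and 7 adjusted over the list alone), with a median of 1.13 (camera adjusted p = 3.45e-22, and adjusted p = 0.214 with an estimated correlation). Olfr536, from 23.4 ± 5.25 to 153 ± 18.4 CPM, Olfr741, Olfr1348 and Olfr1346 had the smallest adjusted p. Of 11 trace amine receptors 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0434, and adjusted p = 0.567 with an estimated correlation). Of 23 immature neuron genes 5 rose and 7 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.615). Hdac9 (1.93 ± 0.16) and Stmn4 (1.86 ± 0.25) rose and Cxcr4 (-1.12 ± 0.13) fell.

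Of 19 sustentacular genes 14 rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 2.73e-05, and adjusted p = 0.226 with an estimated correlation). Cyp1a2 (5.53 ± 0.26) and Sec14l3 (3.65 ± 0.19) were among those that rose. Of 33 xenobiotic metabolism genes 23 rose and 2 fell (23 and 2 adjusted over the list alone; camera adjusted p = 2.97e-07, and adjusted p = 0.214 with an estimated correlation). Cyp4b1 (2.71 ± 0.23) and Cyp2e1 (4.02 ± 0.36) were among them. Bowman's gland genes rose in 11 of 21 cases and fell in 3 (11 and 3 adjusted over the list alone), led by Scgb1c1 (4.56 ± 0.19) and Bpifb3 (5.26 ± 0.33; camera adjusted p = 0.0102, and adjusted p = 0.576 with an estimated correlation). Of 14 microvillous cell genes 8 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.00189, and adjusted p = 0.162 with an estimated correlation). Alox5 (2.47 ± 0.26) and Avil (1.40 ± 0.23) rose.

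Of 26 cell cycle genes 25 fell (25 adjusted over the list alone), with a median log2 fold change of -1.12 (camera adjusted p = 5.58e-14, and adjusted p = 0.147 with an estimated correlation). Birc5 (-1.57 ± 0.12), Aurkb (-1.53 ± 0.14) and Plk1 (-1.45 ± 0.14) fell. Of 15 globose basal genes 11 fell (13 adjusted over the list alone), led by Kit (-1.54 ± 0.12) and Tead2 (-1.22 ± 0.14; camera adjusted p = 0.00026, and adjusted p = 0.214 with an estimated correlation). Horizontal basal cell genes fell in 7 of 13 cases and rose in 2 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0393, and adjusted p = 0.576 with an estimated correlation). Cdh3, a cadherin, was at -1.49 ± 0.15. Of 28 Wnt signalling genes 19 fell and 1 rose (19 and 2 adjusted over the list alone), among them Sfrp1 (-1.49 ± 0.15) and Wnt11 (-3.26 ± 0.41; camera adjusted p = 0.00026, and adjusted p = 0.214 with an estimated correlation). Of 20 immediate early genes 11 fell (11 lower and 1 higher adjusted over the list alone), with Nr4a2 at -2.09 ± 0.26 and Fosl2 at -1.66 ± 0.21 (camera adjusted p = 0.00803, and adjusted p = 0.559 with an estimated correlation).

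Markers of other cells that the dissection can hold moved as well. Of 14 endothelial genes 13 fell (14 adjusted over the list alone), with a median of -1.76 (camera adjusted p = 1.08e-07, and adjusted p = 0.214 with an estimated correlation) and Cdh5 at -2.77 ± 0.35. Of 16 genes of respiratory ciliated cells 11 fell and 2 rose (12 and 3 adjusted over the list alone; camera adjusted p = 0.0059, and adjusted p = 0.576 with an estimated correlation). Dnah5, a dynein of cilia, was at -2.23 ± 0.35. Of 14 brain neuron genes 9 fell and 3 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.377), with Gria2 at -6.19 ± 0.88, and their score in WT P0 replicate 1 was 5.39 against 2.71 or less in the other WT P0 libraries. Class II antigen presentation genes H2-Eb1, Cd74 and H2-Aa rose by 2.84 ± 0.33, 2.89 ± 0.34 and 2.95 ± 0.42, within a list where 6 members rose and 4 fell of 19 (6 and 4 adjusted over the list alone; camera adjusted p = 0.14).

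**Figure D2:**
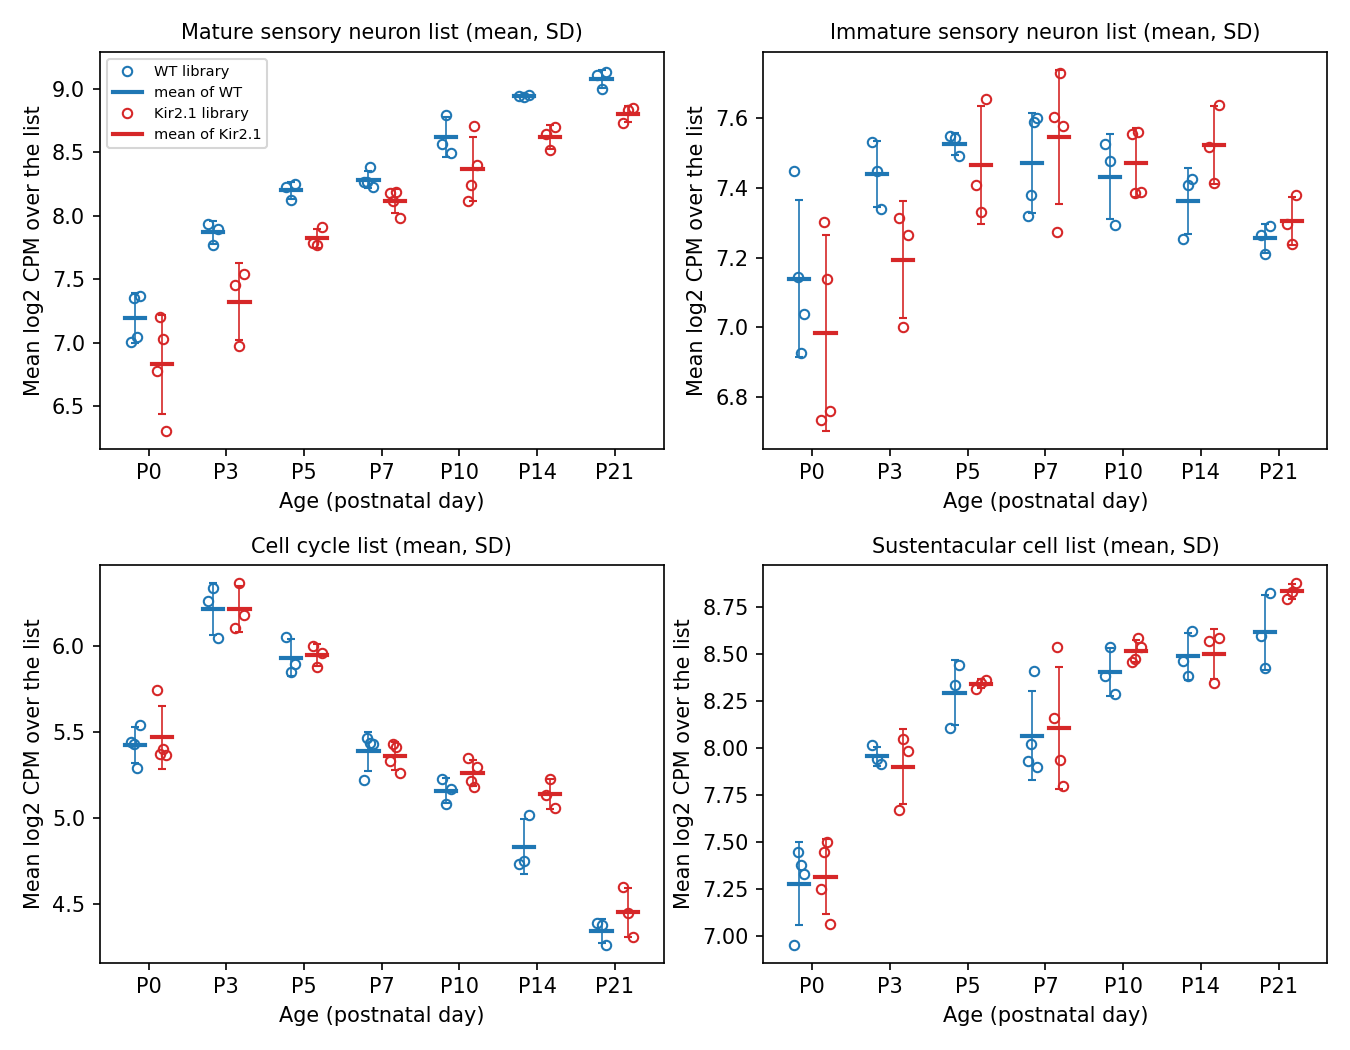
Mean log2 CPM over the mature neuron, immature neuron, cell cycle and sustentacular lists against postnatal age, a circle for each library, a line for each group mean and a bar for the SD, WT in blue and Kir2.1 in red. Omp and the other 25 mature neuron genes rose from P0 to P21 in WT, and 25 of 26 cell cycle genes fell.

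Splitting the time course at P7 gave 4973 genes called between WT P7 and P0, 2293 higher and 2680 lower. By P7 24 of 26 mature neuron genes had risen (24 adjusted over the list alone; camera adjusted p = 1.72e-17, and adjusted p = 0.269 with an estimated correlation). Omp was at a log2 fold change of 1.79 and Cnga2 at 1.27. Of 997 odorant receptors 266 had risen and 3 fallen (271 and 4 adjusted over the list alone; camera adjusted p = 4.04e-12, and adjusted p = 0.571 with an estimated correlation). Interferon-stimulated genes fell in 13 of 25 cases (15 adjusted over the list alone; camera adjusted p = 6.56e-05, and adjusted p = 0.621 with an estimated correlation). Rtp4 was at -2.61. The size of these falls depends on the prefix term, which came from P7 libraries of both genotypes. In Kir P7 the cry6 libraries scored 5.81 and 5.18 on this list, and the low-Kcnj2 cry4 and cry3 libraries 2.19 and 2.39. In WT P7 the cry6 libraries scored 2.04 and 2.08, and the cry4 and cry3 libraries 2.30 and 2.33. The term may thus overstate the fall in WT, where P0 libraries scored 2.35 to 3.37. Of 8 genes of the mitochondrial genome 6 fell (7 adjusted over the list alone; camera adjusted p = 8.34e-05, and adjusted p = 0.571 with an estimated correlation). The count dropped to 1359 without WT P7 replicate 1, the cry4 library of that group. The split of calls turned to 2928 higher and 1961 lower with upper-quartile factors and to 2771 and 1253 on log2(TPM + 1), where the median gene moved by 0.118.

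Between WT P21 and P7 1583 genes were called, 842 higher and 741 lower. This count stood at 98 (26 higher and 72 lower) without WT P7 replicate 1, and at 1016 and 571 without WT P21 replicates 1 and 3. It was 792 (282 higher and 510 lower) without a filter on low counts and 5491 (2567 and 2924) without the prefix term. With a filter of 1 CPM in 10 libraries 839 were higher and 847 lower. On log2(TPM + 1) it was 959 with 341 higher and 618 lower, and with upper-quartile factors 683 were higher and 854 lower. Any difference among the 7 ages in WT was called for 9883 genes. In Kir, P21 versus P0 called 9704 genes, 4561 higher and 5143 lower. Higher calls outnumbered lower ones there with upper-quartile factors (4992 and 4655) and on log2(TPM + 1) (4564 and 3816).

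Averaged over ages, interferon-stimulated and antigen presentation genes were higher in Kir, and mature neuron genes, odorant receptors and genes raised by sensory neuron activity were lower. Ifit3, an interferon-induced protein, stood at 103 ± 13.1 CPM in Kir P10 (SD, n = 4) and 1.29 ± 1.06 CPM in WT P10 (n = 3). H2-K1, a class I histocompatibility gene, stood at 772 ± 40.4 CPM in Kir P21 (n = 3) and 100 ± 23.8 CPM in WT P21 (n = 3). S100a5, a calcium-binding protein of sensory neurons, stood at 173 ± 37.4 CPM in Kir P10 and 374 ± 55.4 CPM in WT P10. In all, 2073 genes were called, 603 higher and 1470 lower, of which 140 and 82 changed at least 2-fold. Without the 2 Kir P10 libraries with many unmapped reads, left out after seeing the data, 1725 were called, 496 higher and 1229 lower.

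Among called genes of at least 5 CPM whose fitted difference had the same sign at all 7 ages, the 10 largest rises were Kcnj2 and 9 interferon-induced genes. Ifit3b, Ifit3 and Mx1 rose by log2 fold changes of 4.40 ± 0.41, 4.22 ± 0.42 and 3.46 ± 0.37. Irf7, a transcription factor of the interferon response, rose by 3.38 ± 0.27, and Zbp1, a nucleic acid sensor, by 3.00 ± 0.25. Isg15, Oasl1, Iigp1 and Oas1g rose by 2.99 ± 0.27, 2.84 ± 0.29, 2.77 ± 0.26 and 2.76 ± 0.21. Of 25 interferon-stimulated genes 24 rose (24 adjusted over the list alone), with a median of 2.42 (camera adjusted p = 1.71e-65, and 0.00206 with an estimated correlation). Xaf1 and Oas1a rose by 2.42 ± 0.18 and 2.37 ± 0.19. Of 19 antigen presentation genes 17 rose (18 adjusted over the list alone), with a median of 1.38 (camera adjusted p = 1.56e-39, and 0.000318 with an estimated correlation). By adjusted p they were led by Psmb8, an immunoproteasome subunit (1.58 ± 0.11), H2-K1 (1.62 ± 0.12), H2-Q7 (2.97 ± 0.23) and B2m, the class I light chain (1.67 ± 0.12).

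Macrophage markers were higher by less. Of 17 such genes 12 rose (12 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 1.52e-13, and 0.0311 with an estimated correlation). Among them were the complement genes C1qb (0.60 ± 0.08), C1qa (0.50 ± 0.07) and C1qc (0.54 ± 0.08), and Trem2 (0.73 ± 0.12). Of 13 lymphoid genes 2 rose, Cd4 (0.87 ± 0.12) and Lck (0.35 ± 0.11), and 3 adjusted over the list alone (camera adjusted p = 0.00339, and adjusted p = 0.204 with an estimated correlation). No fibroblast gene of 18 was called by edgeR over all genes or adjusted over the list alone, while the list had a median of 0.31 (camera adjusted p = 1.49e-05, and adjusted p = 0.408 with an estimated correlation). Ribosomal protein genes rose in 5 of 30 cases (24 adjusted over the list alone; camera adjusted p = 4.07e-06, and adjusted p = 0.582 with an estimated correlation). Rps6 and Rpl11 rose by 1.08 ± 0.34 and 0.99 ± 0.30. This list stood apart in 2 Kir P10 libraries, described with that age.

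By the same rule the largest falls were Nphs1 (nephrin, an adhesion protein of the immunoglobulin family) at -1.69 ± 0.12, S100a5 at -1.20 ± 0.10, Gucy1b2 (a guanylate cyclase subunit) at -1.16 ± 0.14 and Kirrel2 (an adhesion protein of sensory axons) at -1.09 ± 0.13. With them were 6 odorant receptors, Olfr1321 (-1.15 ± 0.09), Olfr523 (-1.12 ± 0.09), Olfr1325 (-1.06 ± 0.13), Olfr665 (-1.04 ± 0.09), Olfr1258 (-0.98 ± 0.11) and Olfr285 (-0.94 ± 0.17). Adjusted p for these genes was 0.000116 or less. Nphs1 (30458315 to 30487223) and Kirrel2 (30447534 to 30457690) are neighbors on chromosome 7, so their falls may not be separate findings. Of 997 odorant receptors 527 fell and 0 rose by edgeR (651 lower and 4 higher adjusted over the list alone), with a median of -0.45 (camera adjusted p = 4.27e-62, and 0.0197 with an estimated correlation). Of 11 trace amine receptors 6 fell (7 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 1.06e-06, and 0.0311 with an estimated correlation). Taar7a fell the most of the 4 members named, at -1.11 ± 0.14.

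Of 26 mature neuron genes 19 fell (22 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 3.73e-21, and 0.045 with an estimated correlation). Among them were Slc17a6, the glutamate transporter of these neurons (-0.62 ± 0.07), Omp (-0.54 ± 0.07), Pde1c (-0.50 ± 0.05) and Stoml3 (-0.44 ± 0.06). Of 21 genes raised by sensory neuron activity 11 fell (11 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 4.21e-08, and 0.0235 with an estimated correlation). They included S100a5, Kirrel2, Epha5 (-0.66 ± 0.07) and Pcp4l1 (-0.62 ± 0.08). Immediate early genes, which also respond to activity, were not called as a list, with 1 of 20 lower (0 adjusted over the list alone), a median of 0.02 and camera adjusted p = 0.606. Of 10 genes listed as lowered by activity 3 fell, and 3 adjusted over the list alone (camera adjusted p = 0.0839). They were Sema7a (-0.77 ± 0.08), Robo2 (-0.28 ± 0.07) and Hist2h2be (-0.20 ± 0.05). Lower activity would raise genes that activity lowers, so these falls go against it if the list is right. Membership of this list and of the activity-raised list was taken as given and activity was not measured, so neither list decides. Ion channel and excitability genes fell in 9 of 29 cases (16 lower and 1 higher adjusted over the list alone), Atp1b1 (-0.26 ± 0.04) among them (camera adjusted p = 1.06e-06, and adjusted p = 0.145 with an estimated correlation). Axon guidance genes fell in 10 of 40 cases (14 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00577, and adjusted p = 0.582 with an estimated correlation). No cell cycle gene of 26 was called by edgeR or adjusted over the list alone (median 0.08; camera adjusted p = 0.000804, and adjusted p = 0.451 with an estimated correlation). Of the 35 lists 17 were called, and 7 of them with an estimated correlation.

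**Figure D3:**
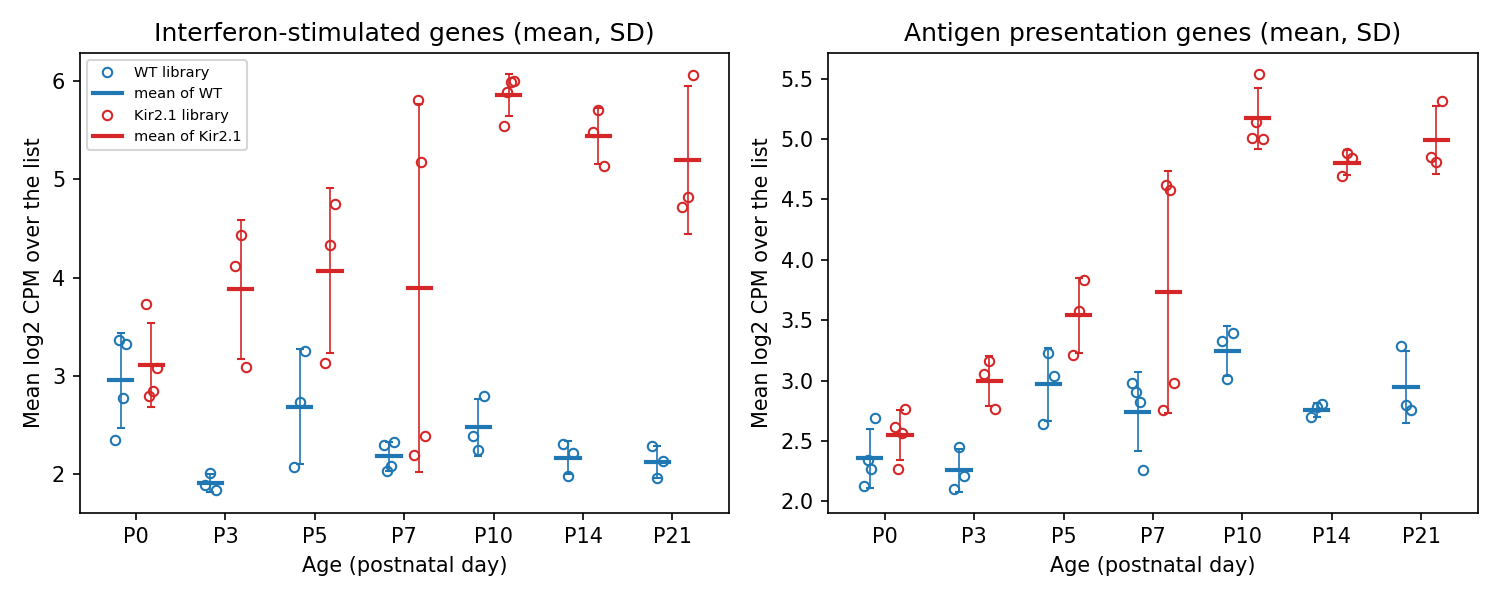
Mean log2 CPM over the interferon-stimulated (left) and antigen presentation (right) lists against postnatal age, a circle for each library, a line for each group mean and a bar for the SD, WT in blue and Kir2.1 in red. At P10, P14 and P21 each Kir library lies above the WT libraries, and 5 Kir libraries, of P0, P5 and P7, lie at or below the highest WT library of their age in the interferon list.

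Single ages held fewer calls. At P0 196 genes were called, 69 higher and 127 lower in Kir. Kcnj2 (3.35 ± 0.48), Ptgfr (a prostaglandin receptor, 1.28 ± 0.25) and Tbx15 (a mesenchymal transcription factor, 1.16 ± 0.26) were higher, and Nefl (a neurofilament, -1.94 ± 0.42), S100a5 (-1.64 ± 0.25) and Kcng1 (a potassium channel subunit, -1.27 ± 0.31) were lower. Of 13 skeletal muscle genes 8 were higher (11 adjusted over the list alone; camera adjusted p = 0.00124, and adjusted p = 0.56 with an estimated correlation). Their score was 6.10 in Kir P0 replicate 4 and at most 0.31 in the other 3 Kir libraries. Of 14 brain neuron genes 6 were lower (10 lower and 1 higher adjusted over the list alone; camera adjusted p = 5.65e-06, and adjusted p = 0.234 with an estimated correlation). Their score was 5.39 in WT P0 replicate 1 and at most 2.71 in the other 3 WT libraries. The count was 4 without WT P0 replicate 1, 3 without Kir P0 replicate 4, 399, 493, 335 and 115 without WT replicates 3 and 4 and Kir replicates 2 and 3, and 330 with WT P0 replicate 3 placed in P3. Of the 35 splits of these 8 libraries 28 called as many genes or more, up to 1368.

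At P3 142 genes were called, 32 higher and 110 lower, and 72 with a block of replicate numbers, 33 higher and 39 lower. Kcnj2 (3.64 ± 0.56), Xaf1 (2.76 ± 0.53) and Gbp3, an interferon-induced GTPase (2.69 ± 0.62), were higher, and Nphs1 (-2.04 ± 0.34), Kirrel2 (-1.83 ± 0.36) and Kcng1 (-1.79 ± 0.36) lower. Of 997 odorant receptors 58 fell (13 with the block; 289 adjusted over the list alone, and 181 with the block; camera adjusted p = 1.05e-53, and adjusted p = 0.0915 with an estimated correlation). At the same age 4 of 25 interferon-stimulated genes rose (10 with the block; 23 adjusted over the list alone; camera adjusted p = 1.08e-22, and adjusted p = 0.107 with an estimated correlation). The count was 10 and 44 without WT P3 replicates 1 and 3, 87 and 12 without Kir P3 replicates 1 and 2, and 40 with WT P0 replicate 3 placed here.

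At P5 23 genes were called, 4 higher and 19 lower, with Kcnj2 at 4.35 ± 0.58, Olfr285 at -2.30 ± 0.46, Nphs1 at -1.86 ± 0.32 and S100a5 at -1.76 ± 0.28. At P7 15 genes were called, 11 higher and 4 lower, with Kcnj2 at 3.04 ± 0.52, Olfr1321 at -1.18 ± 0.21, Olfr665 at -1.03 ± 0.22 and Cpn1, a carboxypeptidase, at -0.99 ± 0.20. Among interferon-stimulated genes 0 of 25 were called by edgeR at P5 (82 and 94 genes of all kinds were called by DESeq2 at P5 and P7, and 1125 had an unadjusted p under 0.05 at P5 in edgeR) and 1 at P7. Of these genes 20 and 24 rose adjusted over the list alone (camera adjusted p = 4.37e-27 and 9.15e-58, and with an estimated correlation 0.0974 and 0.00442). The P7 rise lay in Kir replicates 2 and 3, with list scores of 5.81 and 5.18. The low-Kcnj2 replicates 1 and 4 scored 2.19 and 2.39, near the highest WT library at 2.33. Without any single library the P5 count lay between 7 and 11. It was 240, 41 higher and 199 lower, with only the 2 groups in the fit, and 5, 2 higher and 3 lower, on log2(TPM + 1). The P7 count was 0 without WT P7 replicate 2 or 3, against 94 with DESeq2 and 812 genes at an unadjusted p under 0.05 in edgeR. It was 84 without replicate 1 and 69 without replicate 4 of either genotype and 3 and 8 without Kir replicates 2 and 3.

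At P10 620 genes were called, 562 higher and 58 lower. Among genes of at least 5 CPM without overlap between the groups, Ifit3 (6.32 ± 1.08) was among the 3 largest rises, with the ribosomal protein genes Rpl19 (7.54 ± 1.20) and Rps27 (6.78 ± 1.11), and Nphs1 (-1.97 ± 0.28), Kcng1 (-1.30 ± 0.30) and Gucy1b2 (-1.22 ± 0.33) were the largest falls. Of 25 interferon-stimulated genes 24 rose (25 adjusted over the list alone), with a median of 3.63 (camera adjusted p = 2.05e-86, and 0.00031 with an estimated correlation). Of 30 ribosomal protein genes 23 rose (25 adjusted over the list alone; camera adjusted p = 1.26e-27, and adjusted p = 0.144 with an estimated correlation). In Kir P10 replicates 1 and 2 Rpl19 stood at 297 and 289 CPM, in the other cry6 libraries at 0.707 to 1.42 CPM and in the cry4 libraries at 95 to 260 CPM, while its TPM ran from 732 to 1740 over all libraries. These 2 libraries had 17.73% and 33.49% unmapped reads. Left out after seeing the data, they took the count to 163, 154 higher and 9 lower, with 0 of 30 ribosomal protein genes called by edgeR, and leaving out replicate 1 or 2 alone took it to 362 or 371, and leaving out WT P10 replicate 2 or 3 to 373 or 381.

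At P14 235 genes were called, 153 higher and 82 lower, and at P21 151, 130 higher and 21 lower. By the same rule, at P14 Apol9b (6.32 ± 0.85), Ifit3b (6.13 ± 1.14) and Ifit3 (5.52 ± 1.13) led the rises. The falls were led by Nphs1 (33.2 ± 5.51 CPM in WT and 8.43 ± 3.05 CPM in Kir), Olfr1443 (-1.80 ± 0.31) and Olfr1325 (-1.64 ± 0.35). At P21 Oas2 (5.99 ± 0.90), Apol9b (5.93 ± 0.81) and H2-Q6 (5.36 ± 0.62) led the rises and Nphs1 (-1.70 ± 0.30), Olfr522 (-1.59 ± 0.27) and Olfm4 (-1.44 ± 0.28) the falls. Of 25 interferon-stimulated genes 24 rose at P14 (24 adjusted over the list alone) and 22 at P21 (24 higher and 1 lower adjusted over the list alone). At either age 12 of 19 antigen presentation genes rose (15 and 17 adjusted over the list alone). Odorant receptors fell in 44 of 997 cases at P14 (161 adjusted over the list alone; camera adjusted p = 1.27e-40, and adjusted p = 0.0779 with an estimated correlation). At P21 6 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.000548, and adjusted p = 0.839 with an estimated correlation). The P14 count was 143, 151 and 148 without WT replicates 1 and 3 and Kir replicate 2. The P21 count was 92 and 69 without WT replicate 3 and Kir replicate 3. DESeq2 split the P14 calls into 166 higher and 160 lower.

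The change from P0 to P21 differed between genotypes for 50 genes, 48 with a positive and 2 with a negative Kir minus WT difference of the change. Those of smallest adjusted p were Ifi27, an interferon-induced gene (difference in log2 fold change 3.15 ± 0.45), Rtp4 (4.68 ± 0.68), H2-K1 (2.92 ± 0.43), H2-D1 (2.68 ± 0.40) and B2m (2.92 ± 0.45). Rtp4 went from 18.6 ± 6.07 to 3.75 ± 0.145 CPM in WT and from 16.0 ± 3.31 to 83.2 ± 43.5 CPM in Kir. Of 25 interferon-stimulated genes 11 were called (23 adjusted over the list alone), with a median of 3.22 (camera adjusted p = 3.39e-44, and 0.0187 with an estimated correlation). Of 19 antigen presentation genes 9 were called (12 adjusted over the list alone), with a median of 2.30 (camera adjusted p = 6.31e-29, and 0.00287 with an estimated correlation). The genotype difference varied among the 7 ages for 51 genes, of which H2-K1, H2-D1, H2-Q4, B2m and Trim25 had the smallest adjusted p (0.000315, 0.000439, 0.000478, 0.000808 and 0.000808). The 50 genes became 110 with DESeq2, 14 without the prefix term, 28 with a covariate of Y-linked expression. It was 18, 21, 33, 29, 33 and 30 without WT P21 replicates 2, 3 and 1, WT P0 replicate 2, Kir P0 replicate 4 and Kir P21 replicate 3. The 51 became 248 with DESeq2 and 10 without the prefix term. They became 253 and 220 without Kir P10 replicates 3 and 4, 28 and 30 without WT P0 replicates 2 and 4, and 29, 26 and 26 without Kir P0 replicates 2, 3 and 4. Of 100 splits 15 called as many.

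Odorant receptor genes together took 0.187% ± 0.04 of gene counts in WT P0 (SD, n = 4) and 0.468% ± 0.027 in WT P21 (n = 3; exact permutation test, two-sided, p = 0.0571, the smallest possible here with the smaller tail doubled; adjusted p = 0.183). Averaged over ages the share was lower in Kir by a difference of -0.076 percentage points (permutation test within age, two-sided, p = 1e-05, the smallest that 100000 permutations can give). It was lower on average at each of the 7 ages, from 0.134% ± 0.034 against 0.187% at P0 to 0.364% ± 0.083 against 0.525% ± 0.078 at P14 and 0.431% ± 0.09 against 0.468% at P21. The P21 difference rested on Kir replicate 3 (0.327%, the others 0.482% and 0.483%), and without it the share was 0.0145 percentage points higher in Kir. Replicate 3 had Kcnj2 at 1050 CPM, and the others are low-Kcnj2 libraries (209 and 238 CPM). At P7, where the prefix differs too, the low-Kcnj2 libraries had the lower shares (0.216% and 0.178% against 0.255% and 0.251%). At P3 the low-Kcnj2 library, at 0.166%, lay between the others, at 0.132% and 0.177%. No single age passed an exact permutation test after adjustment (adjusted p = 0.183 or more), and 3 against 3 libraries cannot go below 0.1 unadjusted. Within the cry4 ages the mean score of the odorant receptor list differed by -0.515 and within the cry6 ages by -0.284 log2 units.

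**Figure D4:**
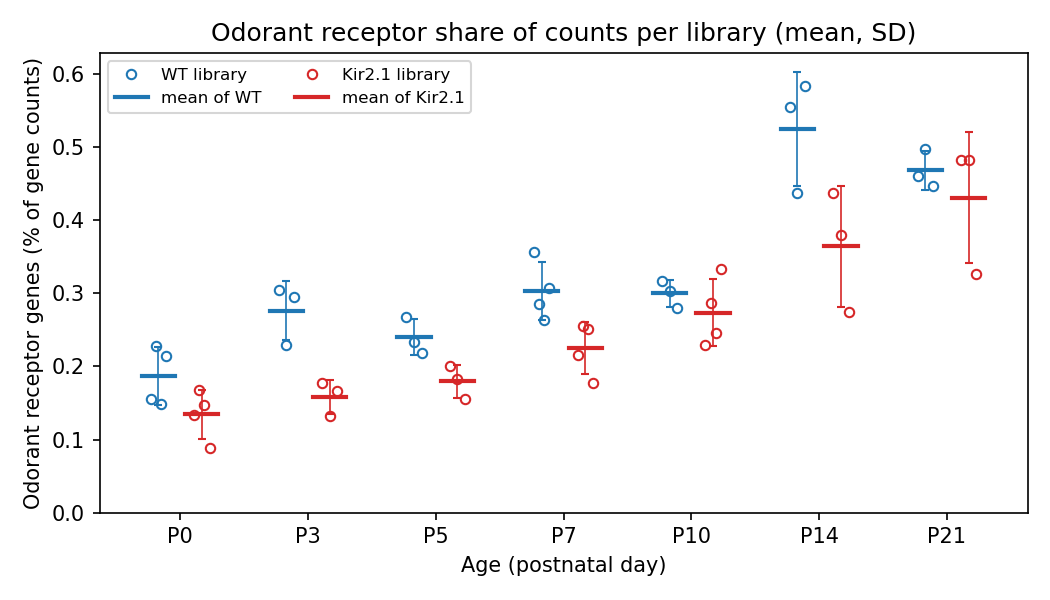
Counts of odorant receptor genes as percent of gene counts against postnatal age, a circle for each library, a line for each group mean and a bar for the SD, WT in blue and Kir2.1 in red. The WT mean goes from 0.187% at P0 to 0.468% at P21, and the Kir mean lies below the WT mean at each age, at P21 through 1 Kir library at 0.327%.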

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

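Tests chosen only after the result was seen were those on the 2 Kir P10 libraries and their TPM, those on the interferon genes, and those of activity-raised genes, S100a5 and Kirrel2 among them, against mature neuron genes. The test on the prefix coefficient was added once the P10 pattern had been seen, though its prediction was written before its result. The other tests in the paragraphs that follow were written before their results.

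Genes higher in Kir at P10 included 23 of 30 ribosomal protein genes, Rpl19 and Rps27 among them, and fewer genes were called without Kir P10 replicates 1 and 2, which had 17.73% and 33.49% unmapped reads. The called ribosomal protein genes had a median log2 fold change of 0.02 without these libraries and 0 of 23 were still called by edgeR, which argues against an effect on these genes in all 4 Kir libraries. Of the 408 genes that lost the call 92.6% had a negative cry6 coefficient, against 45.4% of all genes tested, so counting in these libraries may have followed the way of the cry4 libraries. Of the 154 that held it 9.1% had one, which is no clean contrast. The coefficient rests on P7, where the cry6 Kir libraries had high interferon scores (5.81 and 5.18) and the cry4 Kir library a low one (2.19). That may raise it for interferon-stimulated genes, which were also higher in Kir at P10. On log2(TPM + 1) the median was 0.5 with an SD of 0.5 over the members, and 2 of the 23 were called. This SD is no error of the median, so the values decide nothing on more ribosomal protein RNA in Kir. In the other cry6 libraries 13.41% to 20.58% of reads were multiply mapped, against 6.44% and 5.17% in Kir P10 replicates 1 and 2. Why these libraries differ in mapping is not given in the labels.

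Interferon-stimulated genes, Ifit3, Irf7 and Isg15 among them, were higher in Kir at most ages. The difference in their score exceeded that of the macrophage score by 1.73 log2 units (permutation test within age, two-sided, p = 1e-05, the smallest that 100000 permutations can give), which argues against more macrophages as the whole cause. It was 2.12 within the cry4 ages and 2.38 within the cry6 ages, so it did not rest on the ages of 1 prefix. Both genotypes held the same prefixes at each age, so by design a shift by prefix alone could not have given it. In 5 Kir libraries (P0 replicates 2, 3 and 4 and P5 replicate 1, with Kcnj2 at 439 CPM or more, and P7 replicate 1, with low Kcnj2) the score lay at or below the highest WT library of their age, which argues against a strain difference that is the same at each age. The Kir libraries with low Kcnj2 had lower scores than the others at P3, P7 and P21, by a difference of -1.89 on average (exact permutation within age, two-sided, p = 0.0185, the smallest of 54 arrangements) and -1.24 over P3 and P21, too few to test alone, since at P7 (-3.20) low Kcnj2 goes with the prefixes cry4 and cry3; the transgene may give this, but so may libraries of another genotype, and a strain difference that sets in with age and an infection or housing difference stay open.

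Mature neuron genes such as Omp and odorant receptors were lower in Kir. The score differences of sustentacular (0.059), fibroblast (0.302), endothelial (0.045) and olfactory glia genes (-0.109) spread over 0.411. A permutation test of this range within age, upper tail only, gave p = 0.0035. Dilution by the other cells alone would raise all alike. Fewer neurons beside uneven changes of the other cells would not, so a lower share of neurons stays open. The 21 activity-raised genes as a list fell about as far as mature neuron genes (difference -0.024, permutation p = 0.67), as fewer mature neurons may give, while S100a5 and Kirrel2 fell further, by a difference of -0.84 (permutation p = 1e-05), which decides nothing since they were picked from the largest falls. For odorant receptors the difference was -0.116 (permutation p = 0.093), so fewer mature neurons and lower expression per neuron cannot be told apart there. Lower activity, the biological difference the Kir2.1 channel may bring, stays open, with strain.

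A single library stood far from the other 3 of its group in 8 of 55 sets of 4 values (11 quantities), where chance gives about 1 in 20. The ribosomal protein score was 8.02 in WT P7 replicate 1 (nearest 5.88) and 8.10 in Kir P7 replicate 1 (nearest 5.86), the cry4 libraries of that age. The cell cycle score was 5.22 in WT P7 replicate 1 (nearest 5.43) and 5.74 in Kir P0 replicate 1 (nearest 5.40). The macrophage score was 3.47 in WT P0 replicate 4 (nearest 3.02) and 2.85 in Kir P0 replicate 2 (nearest 3.48). The skeletal muscle score was 6.10 in Kir P0 replicate 4 (nearest 0.31), and the brain neuron score was 5.39 in WT P0 replicate 1 (nearest 2.71).

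The change from P0 to P21 differed between genotypes for 50 genes and the genotype difference varied with age for 51. The differences of Ifi27, Rtp4, H2-K1, H2-D1 and B2m were 3.15, 4.68, 2.92, 2.68 and 2.92 log2 units (edgeR adjusted p = 0.000527, 0.000527, 0.000527, 0.000539 and 0.000769). Over all ages the adjusted p was 0.000315 for H2-K1, 0.000439 for H2-D1, 0.000478 for H2-Q4, 0.000808 for B2m and 0.000808 for Trim25. By median difference of the change, interferon-stimulated and antigen presentation genes stood at 3.22 and 2.30 and held with an estimated correlation (adjusted p = 0.0187 and 0.00287). The other lists called by camera lost the call: immature neuron 0.17 (adjusted p = 0.746 with an estimated correlation), microvillous 0.21 (0.606), activity-raised 0.16 (0.708), xenobiotic 0.19 (0.746), erythroid 0.71 (0.678), macrophage 0.29 (0.746), bone and cartilage -0.83 (0.678), fibroblast -0.83 (0.746), brain neuron 0.85 (0.746), odorant receptor 0.29 (0.746) and trace amine receptor 1.08 (0.11). Without the 5 low-Kcnj2 libraries, an alternative chosen after seeing the data, the erythroid, macrophage and odorant receptor medians changed sign, to -0.97, -0.25 and -0.17.

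Unmapped reads, which entered no test, made up 17.73% of Kir P10 replicate 1, 33.49% of Kir P10 replicate 2 and 16.36% of Kir P14 replicate 3, against at most 14.88% in a WT library.

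Other splits of the same libraries tested whether chance alone gives as many calls. Only the real split of 35 reached its count for WT P21 versus P0 (10078 genes, highest other 7951) and Kir P21 versus P0 (9704, 8161). The same held for WT P7 versus P0 (4973, 1847) and WT P21 versus P7 (1583, 1198). Of 100 draws 1, the real one, reached it for WT age (9883, 4946) and the mean genotype difference (2073, 322). For WT P21 versus P0, Kir P21 versus P0 and the mean genotype difference the share was under 0.05, unadjusted over comparisons, which argues against chance. This holds between libraries, which may not each come from their own animal. For WT P7 versus P0, WT P21 versus P7 and WT age the splits move libraries of different prefixes between ages. They break the tie of age and prefix that the real split keeps, so they cannot decide there. For the change from P0 to P21 3 of 100 draws reached the count (50, highest other 96). These draws permute genotype at every age and so remove the mean genotype difference as well. They thus cannot exclude chance for a difference in the change alone. Chance cannot be excluded for P0 (28 of 35, with 196 genes and 1368 as the highest other) or P7 (5 of 35, 15 and 2819). Nor can it for P10 (4 of 35, 620 and 920) or the variation with age (15 of 100, 51 and 629). The P7 split of 2819 genes parts replicates 1 and 4 (cry4 and cry3) from 2 and 3 (cry6), and the larger P10 splits set Kir replicates 1 and 2 apart, so both point to a structure of the samples. At P3 (142, highest other 0), P5 (23, 0), P14 (235, 1) and P21 (151, 1) 10 splits are too few for a share under 0.05. At P3, where the numbers were read as pairs, the real split parts all 3 pairs, as do 3 others. The highest other was 0 among these and among the 6 that part 1 pair.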

How the results depend on the processing

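Leaving out the 2 Kir P10 libraries or the 5 Kir libraries with Kcnj2 under 250 CPM, and counting calls without ribosomal protein genes, were chosen after seeing the data. The other alternatives were planned. Over the 262 results on named genes, 7524 of 7943 values kept direction and side of the threshold, 413 lost the call, 2 gained it and 4 reversed, and 56 results lost the call under some setting. Reversed were Slc4a1 in WT P21 versus P0, -0.15 on log2(TPM + 0.1), and Pax5, 0.31 on log2(TPM + 1), 0.11 on log2(TPM + 0.1) and 0.31 without a filter. Counts of called genes that moved over 1.5 times were as follows, and the cause was not tested. Without a filter: 792 for WT P21 versus P7, 44 at P0, 15 at P5 and 8 at P7, and 23 at P7 with 1 CPM in 10 libraries. With DESeq2: 110 for the change from P0 to P21, 248 for variation with age, 295 at P0, 345 at P3, 82 at P5 and 94 at P7. On log2(TPM + 1) and log2(TPM + 0.1): 959 and 885 for WT P21 versus P7, 5 and 12 at P0, 5 and 4 at P5, 8 and 8 at P7, 185 and 180 at P10, and 94 at P3 on the first. On TPM without a filter: 80 for variation with age, 1172 for the mean over ages, 19 at P0, 84 at P3, 43 at P5, 79 at P7, 179 at P10 and 241 at P21. Without the prefix term: 5491 for WT P21 versus P7, 14 for the change from P0 to P21, 10 for variation with age, 11 at P5, 73 at P7 and 370 at P10. With only the 2 groups: 1 at P0, 87 at P3, 240 at P5, 0 at P7 (edgeR; 812 genes at an unadjusted p under 0.05 with all groups, 94 with DESeq2) and 203 at P10. With WT P0 replicate 3 in P3: 330 at P0 and 40 at P3. With the Y-linked covariate: 28 for the change from P0 to P21 and 47 at P0. Without the 5 low-Kcnj2 libraries: 110 for the change from P0 to P21, 113 for variation with age, 93 at P0, 218 at P3, 37 at P5 and 118 at P7. Without the 2 Kir P10 libraries: 163 at P10. With an estimated correlation 0 of 18 lists stayed called for WT P21 versus P0, 7 of 17 for the mean over ages and 2 of 13 for the change from P0 to P21.

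Higher and lower calls split otherwise under some scalings and filters. Kir P21 versus P0 gave 4578 and 3817 on log2(TPM + 0.1) (4561 and 5143 on counts). WT P21 versus P0 gave 4906 and 3842 on log2(TPM + 0.1) and 5803 and 3817 on unfiltered TPM (4757 and 5321 on counts). WT P7 versus P0 gave 2928 and 1961 with upper-quartile factors and 1846 and 1583 without a filter (2293 and 2680). On TPM it gave 2771 and 1253, 2666 and 1173 and 3170 and 1117, where the median gene shifted by 0.118 and 0.149 in the first 2. WT P21 versus P7 gave 341 and 618, 264 and 621 and 389 and 1027 on TPM (842 and 741). On unfiltered TPM the change from P0 to P21 gave 39 and 19 (48 and 2), P0 10 and 9 (69 and 127), P3 28 and 56 (32 and 110), P5 19 and 24 (4 and 19), P7 44 and 35 (11 and 4) and P21 130 and 111 (130 and 21). P5 gave 2 and 3 and 2 and 2 on the filtered TPM, P14 166 and 160 with DESeq2 and 144 and 145 and 135 and 44 on TPM (153 and 82), and P21 152 and 63 with DESeq2.

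Without any single library the counts ran from 8826 to 9920 (WT P21 versus P0), 1359 to 5304 (WT P7 versus P0), 98 to 1767 (WT P21 versus P7), 9006 to 10103 (WT age), 8287 to 9790 (Kir P21 versus P0), 18 to 60 (change from P0 to P21), 26 to 253 (variation with age), 1774 to 2335 (mean over ages), 3 to 493 (P0), 10 to 161 (P3), 7 to 11 (P5), 0 to 84 (P7), 362 to 913 (P10), 143 to 215 (P14) and 69 to 151 (P21). Kcnj2 ran from 3.47 to 3.72. The difference in odorant receptor share ran from 0.267 to 0.296 (WT P21 versus P0) and, for Kir minus WT, from -0.0646 to -0.0367 (P0), -0.141 to -0.104 (P3), -0.0716 to -0.0467 (P5), -0.0907 to -0.0595 (P7), -0.0461 to -0.0114 (P10), -0.205 to -0.116 (P14) and -0.0637 to 0.0145 (P21).

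A block of replicate numbers gave 6 genes at P0, 72 at P3, 151 at P14 and 115 at P21. Libraries of the same number deviated together by over 0.1 in 6 of 13 pairs (correlations -0.22 to 0.37) and correlated best with their own number in 6. By this measure, which was not tested against chance, the numbers were read as pairs at P3 alone, not at P0, P14 or P21. Chance may give such a match at a single age. At P3 the block changed the call of no gene named at that age, and of the lists by camera only Bowman's gland (adjusted p = 0.0084) and ribosomal protein genes (0.0286) gained a call and none lost it.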

Other observations

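The test of a fixed strain difference on chromosome 2, the genes named there, the windows without gene families and the tests of low-Kcnj2 libraries were chosen only after the results were seen. The other tests in this part were written before their results.

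Genes called between genotypes lay close together in some places. Odorant and trace amine receptor genes, Kcnj2 and genes outside the autosomes and the X chromosome were left out here. Of 265 windows of 10 Mb, 6 held more called genes than the 8% over the genes left (1514 of 18814; Fisher's exact test, adjusted p below 0.05), which may mark regions that differ between the strains. The window on chromosome 2 from 120000001 to 130000000 held 29 of 127 (adjusted p = 5.8e-05), and the others lay on chromosomes 17 (38 of 210, 0.000242), 1 (23 of 115, 0.00337), 18 (26 of 163, 0.0339), 2 from 110000001 to 120000000 (16 of 81, 0.0339) and 7 (20 of 117, 0.045). Clusters of related genes can give the same picture. With 4 families left out (names starting H2-, Ifi2, Trim or Pcdh) 1 window passed, that on chromosome 2 from 120000001 (adjusted p = 2.84e-05), and its neighbor from 110000001 no longer did.

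On chromosome 2 Spred1 (117121374 to 117182279, an inhibitor of Ras signalling) was higher in Kir by 0.97 ± 0.09 and Thbs1 (118111876 to 118127133, thrombospondin 1) by 1.10 ± 0.14 log2 units (edgeR adjusted p = 1.26e-10 and 6.61e-07). Stard9 and Gjd2 were also higher, by 0.73 and 1.02, as was Gatm (edgeR adjusted p = 3.9e-06), and Slc28a2 was lower, at -1.49. Spred1, Thbs1 and Gjd2 lie in the window from 110000001, which did not pass without the families, and Stard9, Gatm and Slc28a2 in the one that did. The tests that follow are on Spred1 and Thbs1 and so do not speak for the window that passed. In 2 Kir libraries, P7 replicates 1 and 4, the mean of Spred1 and Thbs1 lay at or below the highest WT library of their age, too few to decide on a fixed strain difference. Both have low Kcnj2, and all 5 low-Kcnj2 libraries lay below the other Kir libraries of their age: 6.56 against 7.42 and 7.52 at P3, 6.10 and 6.22 against 7.53 and 7.25 at P7, and 6.21 and 6.42 against 8.08 at P21. The mean difference was -1.30 (exact permutation within age, two-sided, p = 0.0185, the smallest of 54 arrangements). Their low values may come from a lower dose, from an effect of the transgene or from another genotype at these genes, and stay open. At P7 the low libraries are those with prefixes cry4 and cry3, while all at P3 and P21 are cry4, where the difference was -1.34. Over the 19 Kir libraries with higher Kcnj2 their age-centred level had r = 0.2 (permutation p = 0.5) and rho = 0.12 (p = 0.68) with that of Kcnj2, and r = -0.08 without the 2 libraries farthest from the median, which leaves a relation open. The prediction counted a p above 0.05 against a relation, which was wrong, since it left out the 5 low-Kcnj2 libraries, whose values go with one.

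The interferon score had r = -0.09 (permutation p = 0.74) and rho = -0.22 (p = 0.47; both adjusted p = 0.74 over 2 relations) with Kcnj2 over the same 19 age-centred libraries, and r = -0.23 without the 2 farthest. No relation passed the test, which does not exclude one, and its prediction was wrong in the same way. In the 5 low-Kcnj2 libraries the score was 3.09 against 4.12 and 4.43 in the other Kir libraries at P3, 2.19 and 2.39 against 5.81 and 5.18 at P7, and 4.72 and 4.81 against 6.06 at P21 (mean difference -1.89, and -1.24 over P3 and P21, free of the prefix). The highest WT libraries of these ages stood at 2.01, 2.33 and 2.29, so at P3 and P21 the low-Kcnj2 libraries lay above WT.

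Across 16898 genes, which are not independent replicates, the Kir minus WT difference from P3 to P14 had r = -0.343 with the WT change from P0 to P21 (permutation of genotype within age, p = 0.095, permuted range -0.378 to 0.38). By age r was -0.395, -0.337, 0.079, -0.163 and -0.354 at P3, P5, P7, P10 and P14. A delay of development in Kir may give such values but stays undecided.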
